A study of Drosophila melanogaster with 8 samples.

How the data were processed

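Histone H1 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in Oregon-R wild-type Drosophila melanogaster embryos at 14 to 16 h of development. The series has 8 libraries, 4 from H1 immunoprecipitation and 4 from input chromatin, and each input label names the region list of the immunoprecipitated library with the same replicate number. Per the labels' protocols, embryos were fixed with formaldehyde, chromatin was incubated with antibody and collected on beads, and DNA was extracted with phenol and chloroform after digestion with RNase and proteinase. Nothing in the labels says that the 4 replicates came from separate embryo collections, so the spread between them may be partly technical.

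Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The coordinates are those of FlyBase r5, per the file headers, which also give the length of each of the 14 sequences. The program that called the regions, its thresholds and its filters are not given in the sources used here. The deposited files are lists of enriched regions with a start, an end and 1 score per region: a list for each of the 4 immunoprecipitated libraries and 1 combined list for the set of replicates. The score is the authors' own value per region, positive in every list, and its scale and normalization are not given in the sources used here. It was therefore used only to rank and describe regions within a list, as a ratio between sequences of 1 list, and by rank between replicate lists. The shortest region was 1301 bp in each replicate list and 1001 bp in the combined list, so both kinds of list have a lower limit on width. How the replicates were combined is not given in the sources used here. The lists hold no read counts, so the depth of each library is unknown, no counting interval could be given, and the absence of a region does not show the absence of H1.

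The lists were analysed as deposited with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The covered share of a sequence is its covered bases over its full length in the file headers. No correction was made for assembly gaps or for repeats in which reads may not be placed. Uextra, at 29.0 Mb, carried 0 regions in all lists and was left out, which left 13 sequences of 139.7 Mb. The major arms are 2L, 2R, 3L, 3R, 4 and X. The Het sequences are the 6 assembled pieces of heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet), and U holds sequence that could not be placed on a chromosome.

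The covered share of a sequence was compared with that of the other major arms as a log2 ratio per replicate, with an exact two-sided sign-flip permutation test over the 4 values and Benjamini-Hochberg adjustment over 10 comparisons. This test cannot give a p below 0.125. Overlap of 2 lists was measured as shared bases over bases in either list (the Jaccard index) and as the share of regions touched by at least 1 bp. Chance overlap came from circular shifts of one list along each sequence, on bins of 100 bp, with 100000 random combinations of shifts. The shifts keep the widths, the clumping and the total of each sequence, and the smallest p they can give is 1e-05. Chance values for touched regions are means of 200 shifts, and those for the support of the combined list come from 1000 shifts per sequence. Scores of regions that overlapped one-to-one between 2 lists were compared by Spearman's correlation with 100000 permutations.

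The shift test was tested on simulated pairs of clumped lists of 2886 regions. It gave p under 0.05 in 7 of 100 runs with no common regions, in 20 of 20 runs with 5% common regions and in 20 of 20 runs with 20%. The lists with no common regions were not built to share densely covered stretches. The test was therefore not tried on lists that share only such stretches.

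Tests, alternatives and gene lists were fixed before the data were examined. Covered shares in windows of 1 Mb, scores by sequence, and the share of each replicate list inside the combined list were added afterwards. Alternatives were regions at or above the median score of their list, equal numbers of regions per list, major arms only, merging across gaps under 500 bp, overlap of at least 50%, random placement and leaving out each replicate. The only gene table used here is on Release 6, another build than that of the files. The planned comparisons with gene features, transcription start sites, gene lists and base composition were therefore not run, and regions are named by coordinates. The rule for such a case names the 10 regions of highest score in the combined list among those touched by all 4 replicate lists, and the widest combined region of each sequence. The values of the input libraries were not analysed here.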

Results

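Linker histone H1, which binds nucleosomes and the DNA between them, was mapped by ChIP-seq in late embryos of the wild-type Oregon-R strain. The 4 immunoprecipitated libraries gave 2820, 2185, 2886 and 3410 enriched regions for replicates 1 to 4. The mean was 2825 ± 502 regions (SD, n = 4), which covered 3.35% ± 0.64 (SD, n = 4) of the 139.7 Mb considered. The median region was 1528 ± 14.1 bp wide (SD, n = 4). The authors' combined list held 16190 regions with a median width of 1568 bp, the widest of 12533 bp, and covered 21.8% of the same sequence, 6.52 times the mean of the replicate lists. Read depth is unknown, so the lists show where enrichment was called and not where H1 was absent.

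The first question was how H1-enriched regions are spread over the chromosomes. Heterochromatin of chromosome 3 was the most densely covered of the 13 sequences with regions. Regions covered 5.91% ± 1.42 of 3LHet and 5.67% ± 1.59 of 3RHet (SD, n = 4), against 3.33% ± 0.61 of the 6 major arms together. The 2 sequences together stood 1.72-fold above the major arms, with a log2 ratio of 0.78 ± 0.14 (SD, n = 4) that was positive in 4 of 4 replicates. The plan did not name this pair, and its members are the most covered in these same data, which favours a high ratio. All 6 Het sequences together were covered at 4.69% ± 1.22 (SD, n = 4), a log2 ratio of 0.48 ± 0.12. Of these 6, XHet and YHet lay below the major arms in 4 of 4 replicates, at 1.84% ± 0.93 and 1.29% ± 0.73, and 2LHet and 2RHet in 2 of 4, at 2.89% ± 1.52 and 3.74% ± 1.10 (SD, n = 4). In the combined list XHet, YHet, 2LHet and 2RHet were covered at 14.6%, 10.8%, 14.9% and 26.1%. The heterochromatin of chromosome 2 showed no common direction: 2LHet and 2RHet together had a log2 ratio of 0.10 ± 0.24 (SD, n = 4) and lay below the major arms in 2 of 4 replicates. In the combined list 3RHet and 3LHet were covered at 33.3% and 33.2%, and the major arms at 21.9%. Lengths were not corrected for gaps or repeats, so low shares on Het sequences and on U do not by themselves show less H1.

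Chromosome 4, the small autosome known for its heterochromatin-like chromatin, was the least covered of the 13 sequences. Its 1.35 Mb carried 1, 3, 2 and 6 regions in replicates 1 to 4, which covered 0.34% ± 0.22 (SD, n = 4). The log2 ratio to the other major arms was -3.54 ± 1.02 (SD, n = 4), negative in 4 of 4 replicates. The combined list had 52 regions on chromosome 4 and covered 5.17% of it, 4.27-fold less than the other major arms. The X chromosome was covered at 1.81% ± 0.29 and the other major arms at 3.67% ± 0.69 (SD, n = 4), a 2.02-fold difference with a log2 ratio of -1.01 ± 0.12 in the same direction in 4 of 4 replicates. With only the regions at or above the median score of each list, the X ratio shrank to -0.19 ± 0.20 (SD, n = 4) on the log2 scale. Among the autosomal arms, 3R and 2L were covered at 4.22% ± 0.73 and 4.14% ± 0.82, 3L at 3.45% ± 0.66 and 2R at 2.91% ± 0.59 (SD, n = 4). Unplaced sequence (U) was covered at 2.33% ± 0.51 (SD, n = 4). For 9 of the 10 sequence comparisons the exact sign-flip permutation test gave a two-sided p of 0.125, adjusted 0.139, the smallest that 4 replicates allow, so none could pass 0.05. For 2LHet and 2RHet together the exact p was 0.5.

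**Figure D1:**
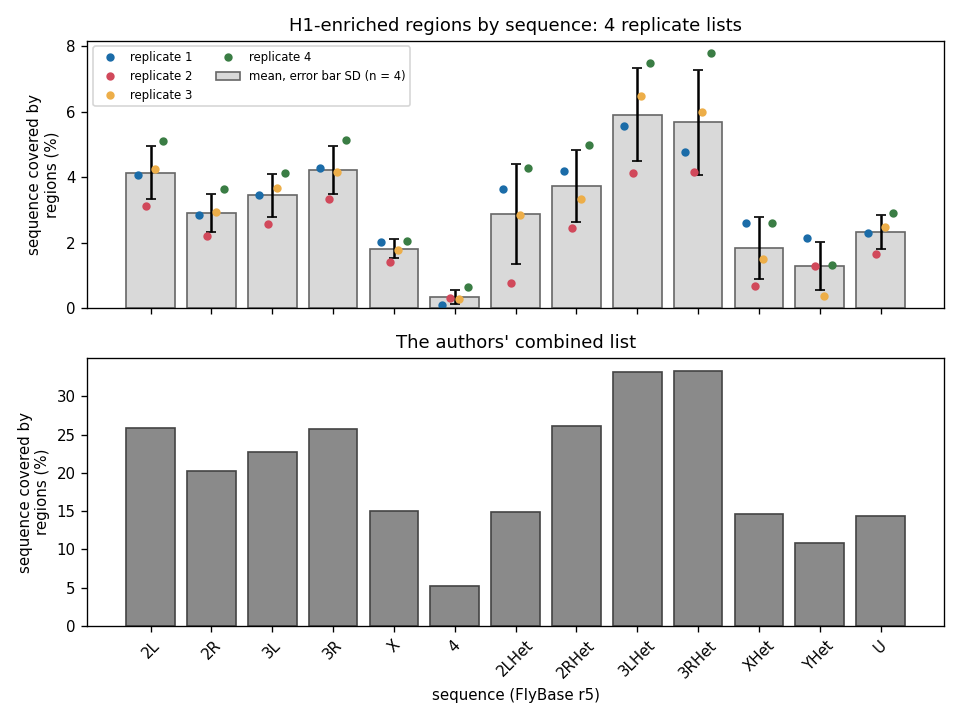
Percent of each FlyBase r5 sequence covered by H1-enriched regions; the upper panel shows the 4 replicate lists as points with their mean (bar) and SD, and the lower panel the authors' combined list. 3LHet and 3RHet stand highest, at means of 5.91% and 5.67%, and chromosome 4 lowest, at 0.34%.

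The score that the authors gave each region also differed between sequences. On the X chromosome the median score was 1.16 ± 0.03 times that of 2L, 2R, 3L and 3R (SD, n = 4), with a range of 1.12 to 1.19, although fewer regions were called there. On YHet, with 1 to 4 regions per replicate list, the ratio was 1.95 ± 0.32 (SD, n = 4), and in the combined list it was 2.06 over 26 regions. Chromosome 4 had a ratio of 1.03 ± 0.18 (SD, n = 4), and 0.99 in the combined list. The larger autosomal Het sequences had ratios of 1.03 ± 0.03 for 3LHet, 1.03 ± 0.02 for 3RHet and 1.01 ± 0.02 for 2RHet (SD, n = 4). The ratio of 2LHet, with 2 to 10 regions per replicate list, was 1.09 ± 0.04 (SD, n = 4), and 1.18 in the combined list, above the 1.15 of X there. U had a ratio of 1.18 ± 0.08 (SD, n = 4), and 1.45 in the combined list. The X, XHet, YHet, U, 2LHet and 3RHet ratios were above 1 in 4 of 4 replicates, for which the exact sign-flip permutation test gave a two-sided p of 0.125, its smallest value, and 0.188 after adjustment over 9 sequences. For chromosome 4 the exact p was 0.875.

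**Figure D2:**
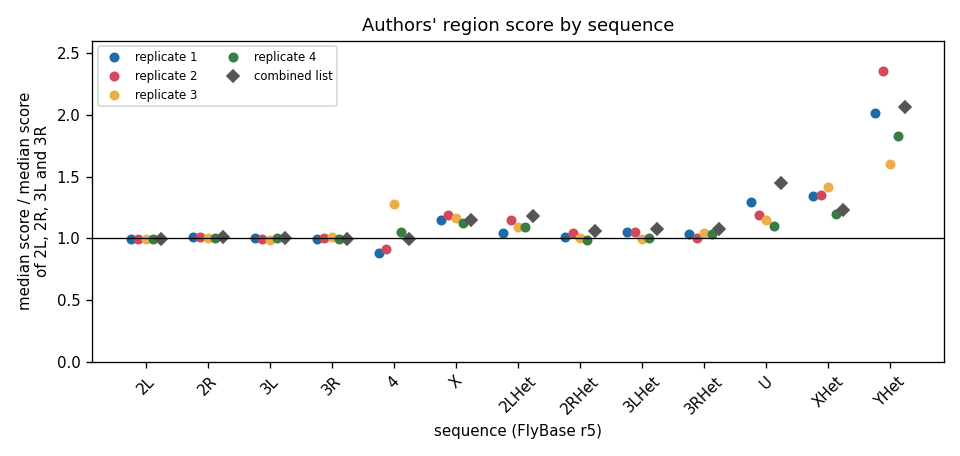
Median region score of each sequence divided by the median score of 2L, 2R, 3L and 3R in the same list; circles are the 4 replicate lists and diamonds the combined list. X lies between 1.12 and 1.19 in the replicate lists, and YHet has a mean of 1.95.

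Along the arms, H1 regions were concentrated in blocks that recurred between replicates. The most densely covered window of 1 Mb was 2L 17000001-18000000, at 9.30% ± 2.34 in the replicate lists (SD, n = 4) and 49.4% in the combined list. It was followed in the combined list by 2L 15000001-16000000 at 44.3%, 3R 23000001-24000000 at 42.4% and 3R 3000001-4000000 at 39.9%. The replicate lists covered those windows at 8.75% ± 1.00, 8.04% ± 1.23 and 6.50% ± 1.37 (SD, n = 4). The least covered windows of the combined list were the first of 3L, at 0.98% ± 0.61 in the replicate lists and 7.87% in the combined list, and X 2000001-3000000, at 0.83% ± 0.41 and 8.22% (SD, n = 4). Across the 117 windows of 2L, 2R, 3L, 3R and X, the covered shares of 2 replicates correlated with Pearson's r between 0.84 and 0.87 and Spearman's rho between 0.80 and 0.84 over the 6 pairs. On the autosomal arms alone r lay between 0.82 and 0.85. Windows are not independent replicates, so no p is given.

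**Figure D3:**
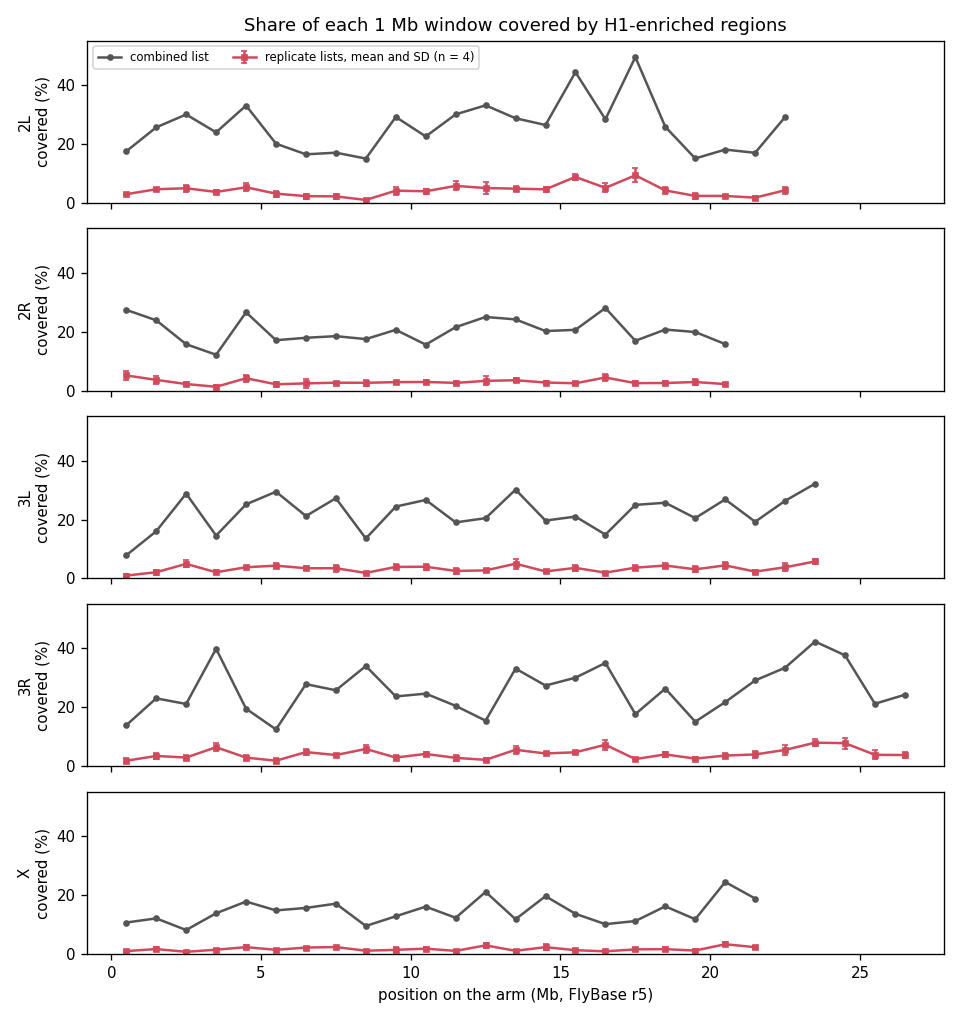
Percent of each 1 Mb window covered by regions (vertical axes) against position in Mb (horizontal axis) on 2L, 2R, 3L, 3R and X, for the combined list (grey) and the replicate lists (red, mean and SD, n = 4). The peak on 2L at 17 to 18 Mb reaches 49.4% in the combined list and 9.30% in the replicate lists.

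The second question was how far single regions recurred between replicates. On average 18.96% ± 2.9 of the regions of one list touched a region of another (SD over 12 ordered pairs), against 7.10% by chance. Over the 6 pairs the Jaccard index was 5.93% ± 0.70 (SD), and the shared bases were 3.12 ± 0.18 times (SD) those of circularly shifted lists. Each pair exceeded chance, with folds from 2.94 for replicates 1 and 2 to 3.39 for replicates 2 and 3, and with p = 1e-05 in the circular-shift permutation test (adjusted 1e-05 over 6 pairs), the smallest it can give. The shifts also move the dense blocks that replicates share. These folds therefore mix shared blocks with the recurrence of single regions, and the test does not separate them. No region had the same start and end in 2 lists, so no library appeared to be deposited more than once. Of all bases covered in any replicate list, 84.4% were covered in 1 list, 13.7% in 2, 1.71% in 3 and 0.17% in all 4. Experiment numbers in the labels fall into 1715 and 1725 for replicates 1 and 2 and 2291 and 2292 for replicates 3 and 4. The folds within these sets, 2.94 and 3.06, lay below the highest of the folds across them, which ran from 2.97 to 3.39.

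Scores recurred weakly. Regions that overlapped one-to-one, 375 to 559 per pair, had Spearman correlations of 0.24 to 0.31 between the scores of 2 replicates, with a permutation p of 1e-05 for each pair (adjusted 1e-05). On 2L, 2R, 3L and 3R alone the correlations were 0.16 to 0.22, with adjusted permutation p between 9e-05 and 0.0011. These correlations are across regions, which are not independent replicates.

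The combined list was then compared with the replicate lists. Of its 16190 regions, 7151 (44.2%) were touched by at least 1 replicate list, against 25.7% by chance, and 9039 by none. Regions touched by all 4 lists numbered 118, where shifted lists gave a mean of 1.13, and 458 were touched by 3 lists, where chance gave 33.9. Each of these counts departed from chance with p = 1e-05 in the circular-shift permutation test (adjusted 1e-05), although the combined list is not independent of the replicates. Here too the shifts move dense blocks that the lists share. The 118 regions were wide, with a median of 4628 bp against 1310 bp for regions touched by no list, and a wider region is touched more readily. With a requirement that at least 50% of the combined region be covered in each list, 7 regions counted as touched by all 4. The 118 regions lay on 3R (36), 2L (29), 3L (24), 3LHet (10), 2R (8), U (5), 2RHet (3), X (2) and 3RHet (1).

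**Figure D4:**
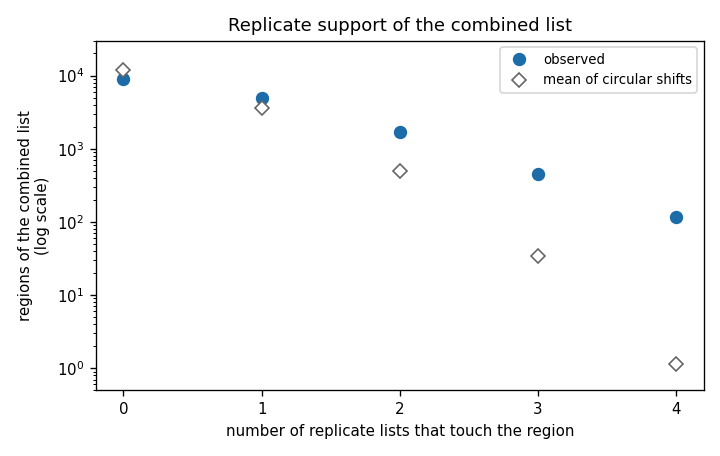
Regions of the combined list (vertical axis, log scale) by the number of replicate lists that touch them (horizontal axis), observed (circles) and as the mean of circular shifts (diamonds). All 4 lists touched 118 regions, against 1.13 in shifted lists.

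The 10 highest-scoring of these 118 regions had scores between 0.50 and 0.57. Chromosome arm 3L held 3 of them, at 22518914-22522058, 24353783-24358426 and 23444491-23452682, all towards the centromere end of the arm. Arm 3R held 3, at 13349126-13353482, 1880517-1884744 and 16259121-16263785. Of these, 1880517-1884744 lay within the 2 Mb at the centromere-near end of that arm. The others were X 22277896-22282060, close to the centromere-near end of that arm, 3LHet 1996075-2001247, 2L 16974116-16976519 and U 3130904-3133485. The highest score, 0.574, belonged to the 3145 bp region at 3L 22518914-22522058, and the widest of the 10, at 3L 23444491-23452682, spanned 8192 bp. Genes at these positions were not analysed here.

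Of the widest combined region of each of the 13 sequences, 2 were touched by all 4 replicate lists and 2 by none. The widest in the genome, 3L 2007295-2019827, spanned 12533 bp and was touched by replicates 1, 3 and 4. The widest of 3R, 23580186-23592096, spanned 11911 bp and was touched by replicates 1, 2 and 4. On 2R the region 851626-861895 (10270 bp) and on 3LHet the region 1968818-1978643 (9826 bp) were touched by all 4. On 2L 17977729-17987987 (10259 bp) and U 405544-415776 (10233 bp), replicates 1, 3 and 4 had regions. On 2RHet 693717-704297 (10581 bp) only replicates 1 and 3 had regions, and on 2LHet 189161-194256 (5096 bp) replicates 1, 3 and 4 did. The widest regions of X (6314236-6321039, 6804 bp) and XHet (142273-146810, 4538 bp) were touched by replicate 1 alone, and that of 3RHet (706807-713550, 6744 bp) by replicate 4 alone. Those of chromosome 4 (1173772-1176139, 2368 bp) and YHet (161397-163732, 2336 bp) were touched by no replicate list.

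In the opposite direction, the combined list held nearly all regions of 2 replicates and fewer of the others. It touched 96.6% of the regions of replicate 1 and 97.0% of those of replicate 4, but 76.2% of replicate 2 and 76.7% of replicate 3, with chance values between 37.7% and 38.2%. By bases, 92.4% and 93.0% of the covered sequence of replicates 1 and 4 lay in combined regions, against 56.4% and 58.5% for replicates 2 and 3. In replicate 3, with 2886 regions, 672 were untouched, and in replicate 1, with 2820 regions, 95 were. No test was run on this difference, which was noticed in the data, since the labels place the 4 libraries in 1 group.

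**Figure D5:**
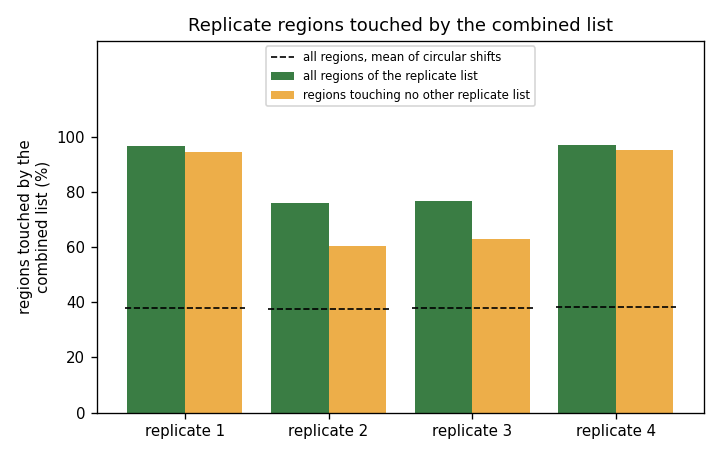
Percent of the regions of each replicate list that the combined list touches (vertical axis), for all regions (green) and for regions that touch no other replicate list (yellow); dashed lines give the mean of circular shifts for all regions. Replicates 1 and 4 lie at 96.6% and 97.0%, replicates 2 and 3 at 76.2% and 76.7%.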

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

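Chosen only after the results were seen were the sequence ratios in the combined list, score correlation on the autosomal arms alone and the settings for the share of each replicate list inside the combined list. Of 73 recomputed values, 16 moved by more than 1 SD of the replicates or pairs, or for counts and the share of combined regions touched by more than 1.5 times. The other 57 were counted as unmoved, but they include values judged by direction alone. Ratios between sequences, for which no exact p of 4 values can pass 0.05, and the gap between replicates in the combined list were judged by direction alone, and 0 reversed. Such a ratio could still move by more than 1 SD, as that of X did from -1.01 ± 0.12 to -0.19 above the median score. With regions at or above the median score, the number of regions per replicate list became 1414.5, their covered share 1.75%, the number of combined regions 8095 and the share of regions touching another list 10.2%, since that setting keeps about 50 in 100 regions by construction, and overlap over chance rose to 3.31. Equal numbers of regions per list gave a covered share of 2.63% and 14.7% of regions touching, because fewer regions were kept. Requiring overlap of 50% of the region lowered the touching share to 11.5%, and reciprocal overlap of 50% to 10.1%. The number of combined regions touched by every list fell from 118 to 7 with overlap of 50%, and was between 195 and 276 when 1 replicate was left out and 3 lists had to touch. Mean score correlation was 0.36 with reciprocal overlap of 50% and 0.19 on the autosomal arms alone, and the cause was not tested. The log2 ratio of X to the other major arms stayed negative throughout, from -1.07 to -0.97 without 1 replicate, but was -0.74 with equal numbers of regions, -0.65 in the combined list and -0.19 above the median score. For chromosome 4 the ratio ran from -3.84 to -3.07 without 1 replicate, and it was not computed with the 2 other score settings, where only 2 and 3 replicate lists had regions there. No paired analysis was possible because the input libraries were not analysed here and no value of theirs could be set beside the region lists. Alternatives for gene features, transcription start sites, gene lists and base composition were not run. Unknown depth limits every statement on sequence with few regions, such as YHet, XHet, 2LHet and chromosome 4.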

Other observations

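Chosen only after the results were seen were the comparison of sequence near and far from the centromere, the description of the highest-scoring regions, the comparisons of overlap between replicate pairs and of region widths, both tests on the score ratio of X, the test on the score ratio of chromosome 4 and the 50% overlap setting for the share of each replicate list inside the combined list. Within the arms, H1 coverage near the centromere was higher than in the rest of the arm on 3L and X, and on 2R without passing 0.05 after adjustment. In the 2 Mb at the centromere-near end of the arm sequence, 3L was covered at 5.74% ± 1.42 and in the rest at 3.24% ± 0.60. X was covered at 3.14% ± 0.44 and 1.69% ± 0.28, and 2R at 4.39% ± 1.36 and 2.75% ± 0.51 (SD, n = 4). Each of these arms was higher near the centromere in 4 of 4 replicates. 2L and 3R were less covered near the centromere in 4 of 4 replicates, at 2.95% ± 0.80 and 4.25% ± 0.82 for 2L and 2.72% ± 0.83 and 4.34% ± 0.74 for 3R (SD, n = 4). Circular shifts of the combined list along each arm gave permutation adjusted p of 0.033 for X, 0.037 for 3L, 0.078 for 2R, 0.28 for 3R and 0.68 for 2L over 5 arms. The 162 highest-scoring combined regions (the top 1%, scores from 1.29) differed from the other combined regions: 61.1% lay on U and 16.7% on Het sequences, against 4.54% and 8.03% of the others. Of these 162, 145 (89.5%) were touched by no replicate list, against 55.5% of the others, and 0 were touched by all 4. Their median width was 1032.5 bp, close to the lower limit of 1001 bp, against 1575.5 bp for the others. That median is below 1301 bp, the shortest region in each replicate list. A narrow region is touched less readily, so the low share touched cannot be told apart from an effect of width. Among 28 measures checked for a replicate far from the other 3, 0 were found, where chance would give 1.4. With 4 values only a very distant replicate can be found, and a split of 2 against 2 cannot. The percent of regions touched by the combined list has such a split, and its gap was 0.02 of the range. Replicate 2 lay furthest out in most of the 28 measures, and other replicates did in the rest. It had 2185 regions against 2820 to 3410, and a covered share of 2.53% against 3.35% to 4.10%. Its median score was 0.70 against 0.56 to 0.59. The check therefore does not show that the replicates are alike.

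The combined list touched more regions of replicates 1 and 4 than of 2 and 3, and narrower regions in replicates 2 and 3 are argued against, because the percent touched in the widest quartile of their regions minus that in the narrowest quartile of replicates 1 and 4 was -8.10 percentage points, although wider regions were touched more often in each list. Weaker calls in replicates 2 and 3 stay open. In the lowest-scoring quartile, 77.9% and 76.7% were touched for replicates 2 and 3 against 96.9% and 97.4% for replicates 1 and 4. These quartiles were set within each list, so they do not match strength between libraries. The contrast of the highest-scoring quartile of replicates 2 and 3 with the lowest-scoring one of replicates 1 and 4 was -27.3 percentage points. High scores were touched less often than low ones in each of the 4 lists, so that contrast cannot decide either. Poorer agreement stays open: pairs of replicate 2 or 3 with 1 or 4 overlapped 1.04 ± 0.05 (SD, 4 pairs) times as much over chance as replicates 1 and 4. Among regions found in 1 replicate list alone, 94.4% and 95.4% were touched for replicates 1 and 4 but 60.3% and 62.8% for replicates 2 and 3, a mean gap of 33.4 percentage points, and the gap over all regions was 34.9 points with overlap of at least 50%. A candidate explanation is that the combined list was made mostly or wholly from replicates 1 and 4, but the lists do not tell whether replicates 2 and 3 were left out or given less weight, and no biological explanation was tested.

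X carried fewer regions than the autosomal arms, with higher scores. A lower copy number of X may raise the score needed for a call. If embryos of both sexes are equally frequent, X has 3 copies and Y 1 for every 4 of an autosome. A threshold that scales with the inverse square root of copies would give ratios of 1.15 for X and 2.00 for Y. That rule was chosen after the ratios were seen. It concerns the score needed for a call, whereas the ratios compare medians of called regions, and the scale of the score is unknown. A match with the rule therefore cannot decide the question. The observed means were 1.16 ± 0.03 for X and 1.95 ± 0.32 for YHet, but XHet, for which 1.15 is predicted too, lay above it at 1.33 ± 0.09 with 1 to 3 regions per replicate list, and autosomal 2LHet, for which copy number predicts 1, stood at 1.09 ± 0.04 (SD, n = 4) and at 1.18 in the combined list, where unplaced U stood at 1.45, so copy number does not account for every raised ratio. Regions in the top 5% of autosomal scores were 3.47 ± 0.95 times as dense on X as on the autosomal arms (SD, n = 4), against 0.51 ± 0.04 for all regions, but this partly restates the higher scores, and at or above the median score X was still less covered in 4 of 4 replicates (log2 ratio -0.40 to -0.01), so a deficit confined to low scores stays open. Lower H1 enrichment on X stays open, since the lowest median score ratio of X over the replicate lists, 1.12, only restates the pattern, and the sex ratio of the embryos was not tested.

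Chromosome 4 had fewer regions than its length would give. Its short length is argued against, because 0.00% of 9122 windows of the same length on 2L, 2R, 3L and 3R, placed every 10 kb, were covered as little in the combined list, and the lowest was covered at 9.48% against 5.17%. Neighbouring windows overlap almost wholly, so 9122 is not a number of independent windows. Lower depth that raises the score needed for a call stays open: the median score ratio of chromosome 4 to the autosomal arms was 0.99 in the combined list (95% bootstrap interval 0.92 to 1.02 over 52 regions, treated as independent), but 0.88 to 1.27 in the replicate lists with 1 to 6 regions, and the rise that lower depth would need is not known. That its chromatin holds less H1, or holds it more evenly so that fewer regions stand out, may each account for the pattern, and the lists do not separate them. No group of the design bears on this.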
